A study of Caenorhabditis elegans with 4 samples.

How the data were processed

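Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in young adult hermaphrodites of Caenorhabditis elegans strain N2, the wild-type laboratory strain. Per the series' labels, the target was RPC-1, the largest subunit of RNA polymerase III, the enzyme that transcribes tRNA genes, 5S rRNA genes and other short non-coding RNA genes. The 4 libraries were 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in each group by the labels. Per the labels' protocols, worms were grown at 20 °C on HB101 bacteria, fixed with 2% formaldehyde and sonicated, and part of the lysate was kept before the precipitation as input DNA. The protocol text names one antibody against a GFP tag and one against RNA polymerase II, and the antibody used for RPC-1 in these untagged worms is not given in the sources used here.

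The 3 deposited files are peak lists, 1 for each ChIP library and 1 for the whole series. Per the file headers, positions are on WormBase WS220, and per the files' own source field the peaks were called with PeakSeq, which scores regions of ChIP reads against a control. The deposited value of each peak is a p-value or q-value from that caller (the files do not say which) between 0 and 0.001, and a value of 0 means one too small to be written. It is called the caller value here, and it was used only to rank peaks within a list. The aligner, the threshold, the control library, the read depth and the way the series-wide list was made are not given in the sources used here. The files hold no read counts, so depth is unknown and a region absent from a list was not called in that library, which is not a measurement of no binding. The input libraries enter only through the authors' peak calling, and ChIP against input was not tested here.

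Each list was sorted by caller value, ties by chromosome and start, and divided into 10 equal groups (deciles) or 5 equal groups (quintiles), numbered from the best to the worst. Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from 100000 circular shifts of one list within each chromosome (one-sided permutation test). The span of each chromosome was taken as the end of its last peak in any list, since chromosome lengths of WS220 were not used here; these spans add up to 100.15 Mb. Shares carry 95% Wilson intervals, which cover counting error only and take peaks as independent, although neighbouring peaks are not. With 2 ChIP libraries there is no measure of spread between samples beyond the comparison of the 2 lists, nothing in the labels says whether they came from separate worm cultures, and every p-value refers to peaks, not to replicates. Shares were compared with Fisher's exact test or an exact binomial test, two-sided; chromosome profiles were compared by a permutation test of their chi-square (100000 draws). Benjamini-Hochberg adjustment was made within each family of tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used; overlap counts were checked against bedtools 2.31.1 and were equal for all 4 pairs of lists tried. On simulated lists of the real sizes (1009 and 2041 peaks) with 500 planted shared peaks, 505 overlaps were found. Of 100 pairs of smaller unrelated lists, tested with fewer shifts, 4 gave a permutation p under the threshold of 0.05. Their peaks were placed at random, without the clustering of the real ones, so this check does not cover clustered lists.

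No gene annotation of WS220 was used here. Of the results planned before the data were examined, 7 needed one and were not run: those on gene classes in peaks, the content of peaks, tRNA isotypes and tRNA positions, values and replicates by class, and B box sequences. Peaks are therefore given by position and not by gene. A gene table of the later assembly WBcel235 was used only for gene names, types and the chromosome each gene is on, to count genes of a class per chromosome; none of its positions was set against a peak. Its nuclear tRNA genes (biotype tRNA) number 612. Regions named in the text were chosen by a rule fixed beforehand, as far as it could be applied without genes: the 10 best and the 5 widest series-wide peaks, and the 5 best peaks of each replicate that the other lacks. The rule's parts on genes were not applied. Alternatives tried were the best 50% of each list, an overlap of at least 50% of the smaller peak, peaks within 250 bp, random placement of peaks, either replicate's list in place of the series-wide one, and series-wide peaks found in both replicates. The division into quintiles, deciles and the best 400 peaks, the X shares of the better and the worse 50% of a list and of shared and unshared peaks (at all ranks and within deciles), the chromosome profiles against gene classes, the middle segment of chromosomes, the set of tRNA genes with other short RNA genes, clusters of peaks within 2 kb, local shifts and merged peaks were chosen after seeing the data.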

Results

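The peak lists of 2 RPC-1 ChIP libraries and of the whole series were compared. ChIP replicate 1 had 1009 peaks over 454 kb (0.454% of the genome span), with a median width of 411 bp. ChIP replicate 2 had 2041 peaks over 903 kb (0.902%), with a median width of 382 bp. The series-wide list held 2173 peaks over 917 kb (0.916%), with a median width of 365 bp. Peaks lay on all 6 nuclear chromosomes in each list. The widest peak was 1903 bp in replicate 1, 3642 bp in replicate 2 and 2887 bp in the series-wide list. Peaks narrower than 50 bp numbered 10, 6 and 67 in the 3 lists. Caller values ran up to 0.00095 in each replicate and 0.000996 in the series-wide list, and 5 peaks of replicate 2 and 7 series-wide peaks had a listed value of 0.

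The first comparison asked how far the repeated ChIP found the same regions. Nearly every region of replicate 1 was also called in replicate 2, whereas most replicate 2 regions were not called in replicate 1. Of the 1009 peaks of replicate 1, 936 (92.8%, 95% interval 91.0 to 94.2) overlapped a peak of replicate 2, against a mean of 19.0 after circular shifts (permutation p = 1e-05, the smallest that 100000 draws can give). Of the 2041 peaks of replicate 2, 919 (45.0%, 42.9 to 47.2) overlapped a peak of replicate 1, also against 19.0 by chance (permutation p = 1e-05). All 404 peaks of the 2 best quintiles of replicate 1 (202 in each) were found in replicate 2, and 153 of 201 (76.1%) in its worst quintile. In replicate 2 the share found in replicate 1 was 99.3% in the best quintile (406 of 409 peaks), 88.5% in quintile 2, 29.9% in quintile 3, 5.64% in quintile 4 and 1.72% in the worst (7 of 408).

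**Figure D1:**
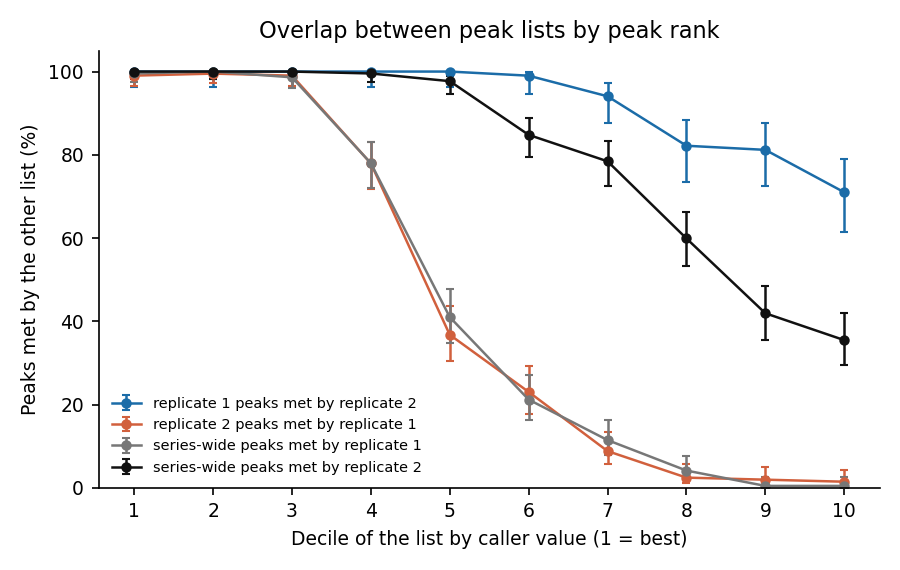
Percentage of peaks met by another list (y axis) in each decile of a list ordered by caller value (x axis, 1 = best); points are shares, bars 95% Wilson intervals, colours the pairs of lists. Replicate 2 peaks met by replicate 1 drop from 99.0% in the best decile to 1.47% in the worst, while replicate 1 peaks met by replicate 2 stay at 71.0% or above.

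At the shared regions the order of peaks was alike in both replicates. Across the 936 shared replicate 1 peaks, caller values correlated with those of the best overlapping replicate 2 peak with Spearman's rho = 0.945 (permutation p = 1e-05, adjusted p = 1e-05, across peaks, which are not independent replicates). Pearson's r of the −log10 values was 0.930 over the 928 pairs with no value of 0 (permutation p = 1e-05, adjusted p = 1e-05). Leaving out the 2 peaks farthest from the median gave rho = 0.945 and r = 0.927. The rho was 0.951 over the 281 pairs on X and 0.928 over the 655 pairs on autosomes. The 100 best peaks of both lists had 82 in common. Shared peaks were wider in replicate 2 in 850 of 936 pairs (90.8%), with median widths of 425 bp in replicate 1 and 543 bp in replicate 2.

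The 10 best series-wide peaks were all called in both replicates, and 7 of them lay on X. Listed at a value of 0 were X:8154165-8156866, X:8623362-8624654, X:9090138-9091790, X:13729614-13731111 and X:16207997-16209967, which ranked between 1 and 6 in replicate 1 and between 2 and 8 in replicate 2. Also at 0 were III:2030722-2033267, ranked 21 in replicate 1 and 1 in replicate 2, and IV:2664035-2666074, ranked 34 and 7. The replicate 2 peaks ranked 1 to 5 all had a value of 0, so their order reflects position and not strength. The same holds for the order of the 7 series-wide peaks at 0. The remaining 3 were X:8969104-8970243, X:8638312-8639385 and II:12541332-12543145. The 5 widest series-wide peaks were II:8418682-8421568 (2887 bp), X:8154165-8156866 (2702 bp), III:2030722-2033267 (2546 bp), IV:2664035-2666074 (2040 bp) and II:7779214-7781209 (1996 bp), and the first 4 of these each covered 2 separate peaks of replicate 1. The last, ranked 129 of the series, was called in replicate 2 (rank 37) and not in replicate 1.

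The 2 lists differed at a few strong regions and many weak ones. The 5 best replicate 2 peaks missing from replicate 1 were I:15064005-15067646 (rank 9), II:7779200-7781241 (rank 37), IV:13353048-13353850 (rank 331), IV:7959411-7960605 (rank 522) and III:12996707-12998112 (rank 600). Of these, I:15064005-15067646 alone was also missing from the series-wide list. The 5 best replicate 1 peaks missing from replicate 2 ranked lower within their list: II:12225281-12226531 (rank 604), X:2089486-2089847 (608), X:2242830-2243138 (681), II:11874619-11874922 (686) and I:14469170-14469451 (688). All 5 were in the series-wide list. On X lay 29.8% of the replicate 2 peaks shared with replicate 1 (274 of 919, interval 26.9 to 32.9) and 11.8% of those not shared (132 of 1122, 10.0 to 13.8; Fisher's exact test, adjusted p = 5.5e-24). In replicate 1, 30.0% of 936 shared and 8.22% of 73 unshared peaks were on X (Fisher's exact test, adjusted p = 2e-05). With the best 50% of each list, the replicate 1 difference was 39.7 points (Fisher's exact test, p = 0.28). Only 3 peaks were then unshared, too few for this test to pass the threshold. Shared peaks also ranked higher, with median ranks of 463 against 1469.5 in replicate 2 and 468.5 against 874 in replicate 1. Within deciles of rank, 274 shared peaks were on X in replicate 2 where 264 were expected (two-sided permutation p = 0.041), and 281 in replicate 1 where 275 were expected (two-sided permutation p = 0.049). Chromosome V held 26% of the unshared replicate 2 peaks and 15.9% of the shared ones, and chromosome IV 21.3% and 15.1%; these differences were not tested.

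The series-wide list was neither the union nor the intersection of the replicate lists. Of its 2173 peaks, 919 (42.3%, 40.2 to 44.4) overlapped peaks of both replicates, 815 (37.5%) a peak of replicate 2 alone, 70 (3.22%) a peak of replicate 1 alone and 369 (17.0%, 15.5 to 18.6) none. Median widths were 544 bp for peaks in both replicates, 278 bp for those in replicate 2 alone, 289 bp for those in replicate 1 alone and 199 bp for those in neither. The best series-wide peak in neither list, V:17935643-17936194, ranked 1239 of 2173, so that every better series-wide peak overlapped a peak of at least 1 replicate; it was picked after its values were seen. When the series-wide and the replicate lists were all reduced to their best 50%, 8.29% of the series-wide peaks met none of the reduced replicate lists. Conversely, 1007 of 1009 replicate 1 peaks (99.8%) and 1725 of 2041 replicate 2 peaks (84.5%) were in the series-wide list. Only 2 replicate 1 peaks and 30 replicate 2 peaks had the same start and end as a series-wide peak.

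The last comparison asked where in the genome the peaks lay and how this relates to the chromosomes that carry tRNA genes, the most numerous class of genes read by RNA polymerase III. X carried many of the strongest peaks and few of the weakest. It held 432 of the 2173 series-wide peaks (19.9%, 18.3 to 21.6), and 17.7% of the genome span (exact binomial test, adjusted p = 0.012). This was 24.4 per Mb, against 21.1 per Mb on all autosomes and from 16.7 on I to 26.8 on III. The density of the whole series-wide list on X thus lay within the range of the autosomes. This also held in replicate 2 (22.9 per Mb, autosomes from 13.0 to 25.3). In replicate 1, X was above every autosome (16.2 per Mb, autosomes from 7.10 to 11.5). In the best quintile of the series-wide list X held 182 of 435 peaks (41.8%, 37.3 to 46.5, exact binomial test, adjusted p = 5.7e-31). This was 10.3 per Mb against 3.07 per Mb on autosomes. Quintiles 2 and 3 had 18.2% and 17.5% of their peaks on X (exact binomial test, adjusted p = 0.96 and 1). In quintile 4 and the worst quintile the shares were 11% and 10.8%, below the X share of the span (exact binomial test, adjusted p = 0.00031 and 0.00027). The share on X was 27.6% in the better 50% of the list and 12.1% in the rest (Fisher's exact test, p = 7.6e-20). Peaks on X were wider, with a median of 476.5 bp against 346 bp on autosomes. Median width also fell with rank in the series-wide list, from 732.5 bp in the best decile to 181 bp in the worst. Widths on X and autosomes were not compared at equal rank, so the difference may follow from rank.

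**Figure D2:**
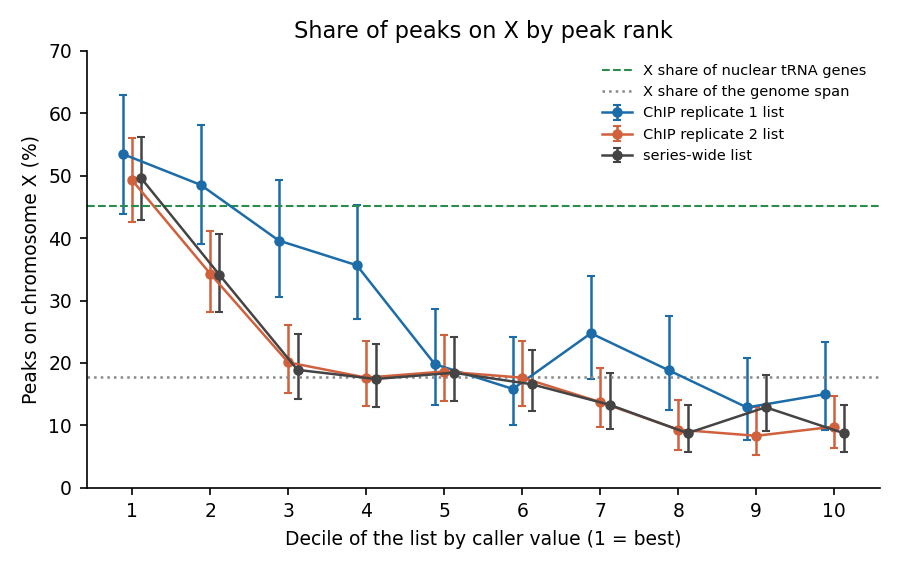
Percentage of peaks on chromosome X (y axis) in each decile of a list ordered by caller value (x axis, 1 = best), for the 2 replicates and the series-wide list; bars are 95% Wilson intervals, the dashed line marks the X share of nuclear tRNA genes (45.1%) and the dotted line that of the genome span (17.7%). All 3 lists begin between 49.3% and 53.5% and end at 15% or below.

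The chromosome profile of the strongest peaks was nearer to that of tRNA genes than to that of any other gene class compared. X carries 276 of the 612 nuclear tRNA genes (45.1%) in the table of assembly WBcel235, and the share of the best quintile of series-wide peaks minus that share was −3.26 percentage points (Newcombe 95% interval −9.29 to 2.84; Fisher's exact test, adjusted p = 0.31). The sign turned, with no p-value past the threshold, in replicate 1 taken alone (5.89 points), in the best 50% of the list (4.44) and for peaks in both replicates (4.36). These sets are shorter, so their best quintiles are stricter cuts, of 202, 218 and 184 peaks against 435. The 4.44 points are those of the best decile of the series-wide list. The 2 deciles that make up the best quintile had 49.5% (43.0 to 56.1) and 34.1% (28.1 to 40.6) of their peaks on X, and the interval of the latter leaves out 45.1%. Over all 6 chromosomes, the part of the best quintile that would have to lie on another chromosome to match the tRNA genes was 6.10 points (permutation test, adjusted p = 0.47). This distance was larger for every other class of at least 100 genes: 35.7 points from tRNA pseudogenes, 32.3 from snoRNA genes, 28.8 from collagen genes, 28.2 from protein-coding genes and 16.3 from miRNA genes, and the best quintile differed from each (permutation test over 36 comparisons, adjusted p between 2e-05 and 0.0015). These classes have between 9.54% (snoRNA genes) and 28.1% (miRNA genes) of their genes on X, so the distances largely restate the X share. Over the autosomes alone, the best quintile was compared with tRNA genes only. The other 4 quintiles differed from the tRNA genes by 26.9 to 34.7 points (permutation test, adjusted p = 2e-05 each). Of the classes compared they were nearest to protein-coding genes, at 7.63 to 11.5 points, and still differed from them (permutation test, adjusted p between 3.6e-05 and 0.04). The genome span was not among the profiles compared, so no distance to chromosome length was computed. By chromosome, quintiles 2 and 3 were both nearer to the span than to protein-coding genes on II, III, V and X. On I both were nearer to protein-coding genes, and on IV only quintile 2 was. Quintile 4 and the worst were nearer to protein-coding genes on I, V and X, and to the span on II, III and IV. For quintiles 2 and 3, being nearest to protein-coding genes among the classes is thus no sign of a link with genes beyond chromosome length. On X, quintiles 2 and 3 (18.2% and 17.5%) were nearer to the 17.7% of the span than to the 13.7% of protein-coding genes. Quintile 4 and the worst (11% and 10.8%) were nearer to the latter. These are comparisons of chromosome shares; whether a given peak lies on a tRNA gene was not tested. The 16 5S rRNA genes, 15 of them on chromosome V, and RNase P RNA (rpr-1, on I), RNase MRP RNA (mrpr-1, on II) and Y RNA (yrn-1, on IV) genes were too few for such a profile.

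**Figure D3:**
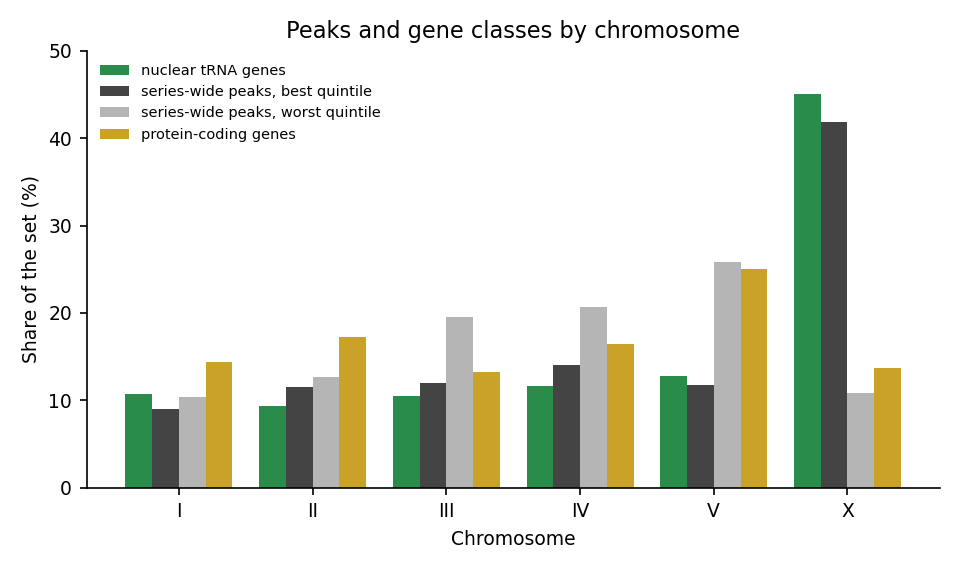
Share of each set (y axis, %) on each chromosome (x axis) for nuclear tRNA genes, the best and the worst quintile of series-wide peaks by caller value, and protein-coding genes; gene counts are from assembly WBcel235. The best quintile has 41.8% of its peaks on X beside 45.1% of the tRNA genes, and the worst quintile has 10.8%.

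In each replicate the best quintile had the largest share on X. The lists differ in length, so that their quintiles cover different ranks. In the best quintile, X held 51.0% of 202 peaks in replicate 1 (44.1 to 57.8) and 41.8% of 409 in replicate 2 (37.1 to 46.6), neither of them past the threshold against the tRNA share (Fisher's exact test, adjusted p = 0.17 and 0.3; Newcombe intervals of the difference −2.02 to 13.7 and −9.42 to 2.92 points). In replicate 1, quintile 4 had 21.8% and the worst quintile 13.9% (9.82 to 19.4), neither past the threshold against the X share of the span (exact binomial test, adjusted p = 0.21 and 0.23). In replicate 2 they had 11.5% and 9.07% (6.65 to 12.2 in the worst), both below that share (exact binomial test, adjusted p = 0.0014 and 4e-06). Over all 6 chromosomes, the best quintile lay 9.94 points from tRNA genes in replicate 1, 7.01 in replicate 2 and 9.18 for series-wide peaks in both. None was past the threshold (permutation test, p = 0.084, 0.32 and 0.12), and all were above the 6.10 of the series-wide list. The profiles of the other gene classes were compared for the series-wide list alone. Taking the 400 best peaks of each list instead, X held 44.8% in replicate 1, 42.0% in replicate 2 and 43.0% in the series-wide list (Fisher's exact test against tRNA genes, adjusted p = 0.95, 0.78 and 0.78). Of the 400 best replicate 1 peaks, 376 overlapped one of the 400 best of replicate 2.

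Along the chromosomes, the strongest peaks lay more often in the middle than those of the next ranks, and in the series-wide list the share rose again among the weakest. When each chromosome's span was cut into 3 equal segments, the middle segment held 38.6% of the best quintile of series-wide peaks (168 of 435, 34.2 to 43.3), 23.7% of quintile 2, 24.4% of quintile 3, 28.7% of quintile 4 and 36.4% of the worst (158 of 434, 32.0 to 41.0). The quintiles differed (permutation test of the chi-square, adjusted p = 4.5e-05 over 9 tests). An even spread would put equal numbers of peaks in the 3 segments. The interval of the best quintile lay just above that even share. On X alone (31.7 to 45.7) and on autosomes alone (32.9 to 44.9) its interval held it. Quintiles 2 and 3 lay well below the even share (19.9 to 27.9 and 20.6 to 28.7), so the contrast lay more in them than in the best quintile. On X alone the share was 38.5% in the best quintile and between 16.5% and 23.4% in the others (permutation test, adjusted p = 0.0002), and the quintiles also differed on autosomes (permutation test, adjusted p = 6e-05), where the best and the worst had nearly the same share, 38.7% and 38.0%, and the others between 25.3% and 30.2%. In replicate 1 the share was 42.6% in the best quintile and 33.2%, 28.2%, 24.3% and 25.4% in the others (permutation test, adjusted p = 0.00045). The worst showed no such rise, but this shorter list hardly reaches the ranks where the series-wide share rose. Of the worst series-wide quintile, replicate 1 met 2 of 434 peaks. In replicate 2 the middle share was 38.9%, 23.8%, 22.8%, 28.4% and 32.4% from the best to the worst (permutation test, adjusted p = 4.5e-05).

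Some peaks came in tight runs. Series-wide, 304 gaps between neighbouring peaks were 2 kb or shorter, against a mean of 113.3 when peaks were placed at random (permutation p = 0.001, the smallest that 1000 placements can give), and 52 runs held 3 or more peaks. No gap was shorter than 204 bp. The longest run was III:3099223-3112382, with 13 series-wide peaks, whose centres lay a median of 1104 bp apart (641 to 1334 bp). Replicate 2 had 12 peaks there (median distance 1107.5 bp) and replicate 1 had 9. In the series-wide list they ranked between 531 and 1040 of 2173, except III:3102939-3103099 at rank 1902. The replicate 2 peak III:3108149-3109160 covered 2 series-wide peaks, III:3108181-3108504 and III:3108824-3109175. The number of peaks and the shortest distance (641 bp series-wide, 969 bp in replicate 2) thus depend on where the caller splits a region. Over the genome, 13 replicate 2 peaks overlapped 2 or more series-wide peaks. The next longest runs had 6 peaks each, at V:7917314-7925076 and II:10541996-10549431.

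**Figure D4:**
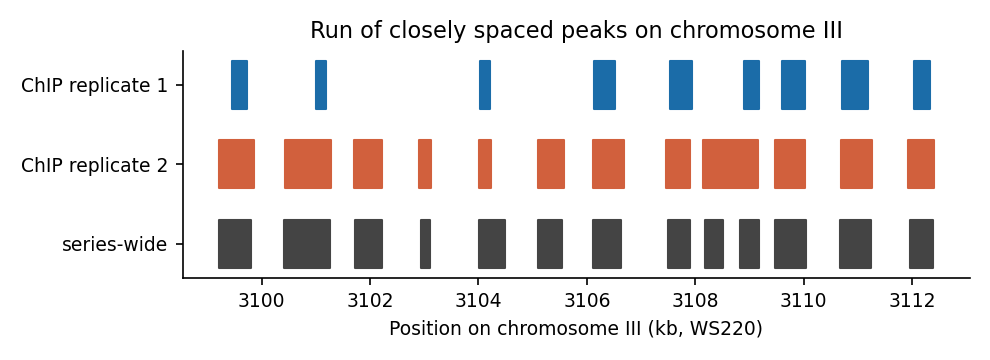
Peaks (boxes, to scale) in the longest run of closely spaced peaks, by position on chromosome III in kb (x axis, WS220), in the 3 lists (rows). Centres of neighbouring series-wide peaks lie 641 to 1334 bp apart and those of replicate 2 peaks 969 to 1325 bp, and 9 replicate 1 peaks fall among them.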

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

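The alternatives that were chosen only after seeing the data were local shifts, merged peaks and the wider gene set; the results on X shares of parts of a list, on chromosome profiles and on the middle segment of chromosomes were also chosen then. Of 51 alternative values for 12 results, 41 kept their direction and their side of the threshold. Another 4, of shares with no test, stayed within the interval of the reported value. Overlap percentages and the profile distance cannot be negative, so for them only the side of the threshold could change. Random placement and local shifts change only the chance overlap, so the observed overlap stayed the same by construction. The difference in X share between the best quintile of peaks and tRNA genes was −3.26 points and not past the threshold. It changed sign to 4.44 in the best 50% of the list and 4.36 for series-wide peaks in both replicates. With the list of replicate 1 it was 5.89, and with that of replicate 2 −3.29. None of these was past the threshold. The sets with a changed sign are shorter, so their best quintiles are stricter cuts, of 218, 184 and 202 peaks against 435. At an equal cut, the 400 best peaks of each list, X held 44.8% in replicate 1, 42.0% in replicate 2 and 43.0% in the series-wide list. No other cause was tested. With the best 50% of each list, the share of series-wide peaks in both replicates moved from 42.3% to 45.0% and the share in neither from 17.0% to 8.29%, with the replicate lists reduced as well. With the best 50%, the X difference between shared and unshared replicate 1 peaks was 39.7 points and no longer past the threshold (Fisher's exact test, p = 0.28). Only 3 peaks were left unshared, too few for this test to pass it. The share of peaks on X was 19.9% in the series-wide list as deposited and 29.9% for series-wide peaks in both replicates. With a replicate's own list in its place, it was 19.9% for replicate 2 and 28.4% for replicate 1. Overlap of the replicates by chance rose from 19.0 to 22.1 peaks with local shifts. Alternatives for the 7 results that were not run were not run either. No paired analysis was possible because the input samples enter here through no values of their own, so the shared replicate numbers of ChIP and input cannot be used. Depth is unknown, so peaks missing from replicate 1 cannot be separated from peaks below its detection limit.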

Other observations

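The tests of signal raised along X, of the X share against tRNA genes in the best quintile and its deciles, of sensitivity in replicate 1 and of how the series-wide list was made were chosen only after their results were seen. One region set apart by its values was I:15064005-15067646, the last peak on chromosome I in any list. It was 3642 bp wide, ranked 9 of 2041 in replicate 2, and was in neither replicate 1 nor the series-wide list, where the last peaks on I ended at 14759699 and 14759747. The right end of chromosome I carries the tandem rRNA gene array in C. elegans; no gene was placed on this peak here. Among the 2042 bp of II:7779200-7781241, ranked 37 in replicate 2, replicate 1 likewise had no peak.

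The share of series-wide peaks on X fell from 41.8% in the best quintile to 10.8% in the worst. Whether signal is raised along the whole of X cannot be told apart from this pattern: the 19.9% of the whole list on X includes the best quintile, the rest of the list had 14.4% on X against 17.7% of the span, and raised signal would also move X peaks out of the low ranks. The chromosome distribution of tRNA genes is a candidate explanation for the best quintile. The interval of its 41.8% (37.3 to 46.5) holds the 45.1% of tRNA genes on X. This cut was chosen after seeing the data. Since the X share falls from 49.5% in the best decile to 19.9% over the whole list, some cut must come near 45.1%. A match at 1 cut is therefore weak evidence. The 253 autosomal peaks of this quintile showed no detected difference from the 336 autosomal tRNA genes over the 5 autosomes (permutation p = 0.49). They were not compared with the lengths of the autosomes, so this test cannot tell tRNA genes from chromosome length. The interval of the best decile, at 49.5% (43.0 to 56.1), also holds 45.1%. That of the next decile, at 34.1% (28.1 to 40.6), leaves it out. The split by decile cannot decide on the explanation, which gives the X share of all tRNA genes and not of each range of ranks. In replicate 1, whose deciles hold fewer peaks, decile 2 had 48.5% on X (39.0 to 58.1), and in replicate 2 34.3% (28.1 to 41.1). Whether the best peaks lie on tRNA genes could be tested with a gene annotation of WS220, which was not used here.

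Replicate 2 lists 2041 peaks and replicate 1 1009. Lower sensitivity in replicate 1 is in line with the 99.3% of the best quintile of replicate 2 that replicate 1 also called, against 1.72% of the worst quintile; without read depths its origin stays open. Strength alone, as ranked by caller value, left a small difference: within deciles of the replicate 2 list, 274 shared peaks lay on X where 264 were expected (two-sided permutation p = 0.041; 0.027 with 50 strata). The shares on X of shared and unshared peaks were 18.9% and 13.3% in decile 4, 18.7% and 18.6% in decile 5, 25.5% and 15.3% in decile 6 and 22.2% and 12.9% in decile 7, where 18 peaks were shared. The test within deciles cannot decide whether peaks that replicate 1 lacks differ in kind as well as in strength. The replicate 2 value is only 1 reading of strength, and its median was 9.71e-40 on X against 2.45e-08 on autosomes. At equal rank, X peaks could still be the stronger ones. The test also took neighbouring peaks as independent. A difference in kind stays a hypothesis from 1 pair of libraries.

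The series-wide list holds 369 peaks that meet no peak of either replicate, which argues against its having been put together from the 2 replicate lists. Calling on pooled reads is a possible explanation that was not tested.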
